A study of Agrobacterium sp. ATCC 31749 with 12 samples.

How the data were processed

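RNA was sequenced from Agrobacterium sp. ATCC 31749 and from its fnrN mutant in 3 conditions, with 2 libraries in each of the 6 groups and 12 in all. Per the labels, libraries were built from total RNA with the Illumina TruSeq RNA kit. TopHat2 and Cufflinks were used by the authors, per the submitters' processing notes. Their versions and settings, the genome build, the annotation and the strandedness are not given in the sources used here. The deposited values were FPKM, estimated by the authors per gene, in 1 table of 4723 rows with 1 column per library. No genome annotation was used here, so positions and product names are not given. Of the rows, 1523 carried a gene symbol or RNA name and 3200 only AGRO numbers, while 640 joined several genes and 332 had a name that occurred more than once. A number after # tells rows of the same name apart in table order. Values of overlapping genes, of joined rows and of near-identical copies could be split by the authors' estimation in ways that cannot be read from the table, so such rows are uncertain.

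The number of fragments per library is unknown. In a class of 21 rows of one length the low values were whole multiples of the value of 1 fragment for 98.9% of 95 values, within a tolerance of 0.1%, and that value lay between 526.9 and 2317 FPKM depending on the library. The class was picked for its high share of whole multiples. The search stopped there, so whether other classes hold such a step was not fully examined. No counts were recovered for the rest, so no count test was run and no interval for counting error is given. In total 415 rows were listed at exactly 0 in at least 1 library, 201 to 338 rows per library, and in each group 66 to 97 rows were at 0 in 1 library and above 100 FPKM in the other. An exact 0 can therefore be a failed estimate, and for such rows values are given per library. Between the replicates of a group the Pearson correlation of log2 values was 0.813 to 0.905, and 0.986 to 0.992 without the rows listed at 0. Replicates lay further apart in the growth phase (median absolute log2 difference 0.195 in the wild type, 0.153 in the mutant) than at 24 h (0.0916 to 0.108).

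Groups and replicate numbers came from the labels. Values were transformed as log2(FPKM + 1), so changes of low genes are understated, and rows with a mean of at least 1 FPKM over all libraries were tested (4664). A cell-means model of the 6 groups was fitted to all 12 libraries with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend) in R 4.3.3, so that groups of 2 shared 1 estimate of the spread with 6 residual degrees of freedom. The 9 comparisons were curdlan phase against growth phase and micro-oxygen against normoxia in each strain, mutant against wild type in each condition, and the difference between strains of the phase and of the micro-oxygen response. All p-values were two-sided and were adjusted over the rows of each comparison by the Benjamini-Hochberg method and called at 0.05. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Shared calls were compared only between comparisons whose group means use no library in common, with the number that independent lists of the same sizes would share. The spread of each row was estimated from all 12 libraries, so a row of small spread tends to be called in several comparisons. The number for independent lists is therefore a reference and not a chance level. Plots were drawn with matplotlib 3.10.9.

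The tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The 26 lists were matched by symbol, so a row can be in a list by its name without sharing the function. Denitrification, transposases and phage genes, and ABC transporters matched no row, and curdlan synthesis (crdS, pssA), FNR and Fix regulators (fixK, fnrN) and general stress regulators (rpoH, dksA) matched 2 rows each and were too short for camera, which needed 3. The other 20 were tested in each comparison, 180 tests in all: cbb3 oxidase, aerobic terminal oxidases, complex I, ATP synthase, heme biosynthesis, ribosomal proteins, flagella and chemotaxis, nitrogen assimilation, tricarboxylic acid cycle, central sugar metabolism, sugar nucleotide supply, other polysaccharides, storage polymers, phosphate, oxidative stress defence, chaperones and proteases, iron, cell division and replication, secretion and conjugation, and ribosomal and transfer RNA. The list of chaperones shares ftsH with that of cell division and rpoH with that of stress regulators. Named were fnrN, the rows of the curdlan, cbb3 and regulator lists, the 8 highest and 8 lowest called changes among rows with a symbol, a mean of at least 10 FPKM and replicates that did not overlap between the groups (5 and 5 without the replicate rule for differences of responses), and up to 4 called members of each list that was called or had 3 or more called members. This gave 255 named genes, of which those with the largest values are printed.

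The linear model and list test were tested on simulated data with each gene's mean over all libraries and its spread within groups, for 4664 genes, with changes added to the wild-type micro-oxygen group and read in its comparison with normoxia. They recovered 80 of 100 genes changed by 1 on the log2 scale and 28 of 100 changed by 0.5, and called 10 of 4444 unchanged genes. With 6 called genes of a list of 20 that was shifted, the calls were 124 in all, of which 8.06% were false. Of 2 simulated lists of 20 genes, camera called the one that was shifted and not the random one. The simulated genes varied independently of each other and with the same spread in every group. The simulation therefore does not test camera on lists of correlated genes, and the correlation estimated from the data reached 0.703 for ribosomal proteins. The alternatives tried were a pseudocount of 0.1, no filter, a mean of at least 10 FPKM, libraries rescaled by median ratios, a replicate block, only the groups compared in the fit, eBayes without trend, and leaving out each library. Further alternatives, chosen after seeing the data, were rows listed at 0 left out, robust eBayes, a log2 change of at least 1, and camera on ranks.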

Results

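Gene expression was measured by RNA sequencing in Agrobacterium sp. ATCC 31749, a bacterium that secretes the glucan curdlan, and in a derivative of it mutated in fnrN. FnrN belongs to the FNR family of oxygen-responsive transcription regulators. Each of the 2 strains was sampled in 3 conditions: the growth phase at 10 h under normoxia, the curdlan-producing phase at 24 h under normoxia, and the curdlan-producing phase at 24 h with micro-oxygen treatment. Each of the 6 groups held 2 libraries, 12 in all. The deposited values were FPKM for 4723 rows, of which 4664 had a mean of at least 1 and were tested. FPKM summed to between 7446000 and 9152000 in the growth-phase libraries and to between 13640000 and 15960000 in the 24 h libraries, while the median FPKM lay between 63.2 and 74.7. The 10 most abundant rows held 57.3 to 77.5% of each sum, and the most abundant row of all 24 h libraries was the 6S RNA. The number of sequenced fragments per library is unknown. Nothing in the labels says that the duplicates came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical. Levels are given as mean FPKM ± SD (n = 2) and changes as log2 changes of FPKM + 1 ± SE, with Benjamini-Hochberg adjusted p-values from limma.

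The mutated gene itself, fnrN, was listed at 225 and 193 FPKM in the wild-type growth phase, at 546 and 516 in the wild-type curdlan phase under normoxia, and at 321 and 303 in the wild type with micro-oxygen. In the mutant libraries fnrN stood at 101 and 120.5 FPKM in the growth phase, at 126 and 122 at 24 h under normoxia, and at 109 and 100.2 with micro-oxygen. It was lower in the mutant in each condition, with log2 changes of -0.91 ± 0.11 (adjusted p = 2.09e-04), -2.09 ± 0.11 (adjusted p = 2.45e-05) and -1.57 ± 0.11 (adjusted p = 1.15e-04). In each of the 3 conditions, both mutant libraries lay below both wild-type libraries. The strain label writes the mutant as deltafnrN, a notation for a deletion, while the genotype label calls it a mutation, and how much of the gene was removed is not given in the sources used here. The mutant signal was not 0, and the part of the gene from which it came cannot be read from 1 value per gene. In the wild type fnrN rose by 1.35 ± 0.11 on the log2 scale from the growth phase to the curdlan phase (adjusted p = 7.58e-06) and fell by 0.77 ± 0.11 with micro-oxygen (adjusted p = 4.5e-04). In the mutant the change of fnrN with phase was 0.17 ± 0.11 (adjusted p = 0.181, and 0.0427 at a change of 0.30 without growth-phase replicate 2) and that with micro-oxygen -0.25 ± 0.11 (adjusted p = 0.0869).

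**Figure D1:**
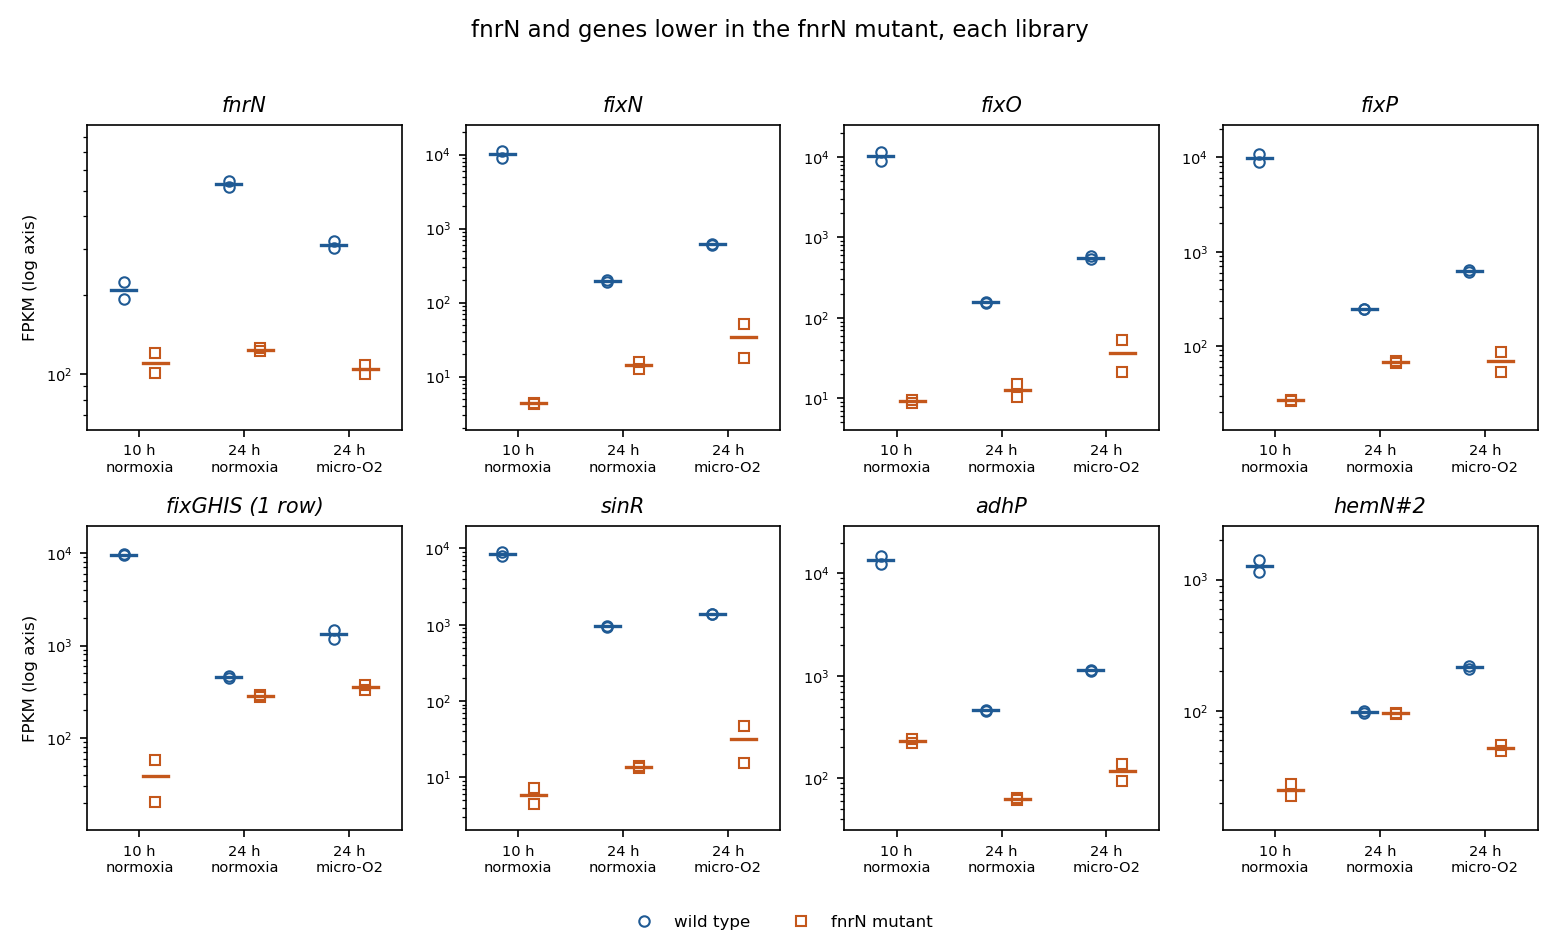
FPKM on a log axis of fnrN and 7 other rows in each library (points) with the group mean (bars), for the wild type (blue circles) and the mutant (orange squares) in the 3 conditions. fixN stood at a mean of 10100 in the wild-type growth phase and 4.35 in the mutant growth phase, while hemN#2 had means of 98.3 and 96.5 in the wild type and the mutant at 24 h under normoxia.

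The first comparison asked what changed in the wild type between growth and curdlan production under normoxia. Transcripts of crdS, the curdlan synthase gene, rose from 26.1 ± 10 to 6003 ± 271 FPKM, a log2 change of 7.84 ± 0.21 (adjusted p = 3.19e-08). Several nitrogen genes rose: amtB, an ammonium transporter, from 95.6 ± 3.95 to 5253 ± 125 (5.77 ± 0.09, adjusted p = 4.1e-09), and glnK, a PII signalling protein, from 107 ± 4.56 to 3083 ± 129 (4.84 ± 0.09). nirB, a subunit of assimilatory nitrite reductase, rose from 5.95 ± 0.07 to 269 ± 1.56 (5.28 ± 0.07). The thiamine synthesis gene thiC rose from 27.1 ± 1.62 to 2051 ± 35.9 FPKM (6.19 ± 0.10), ntrA from 5.23 ± 2.78 to 576 ± 1.43 (6.61 ± 0.25), and exbB, part of the TonB energy-transducing system, from 15.6 ± 3.38 to 512 ± 8.54 (4.97 ± 0.13). Among the falls were fixN and fixO, which encode subunits of the high-affinity cbb3 cytochrome oxidase: fixN dropped from 10100 ± 1720 to 195 ± 7.61 (-5.68 ± 0.40, adjusted p = 4.08e-06) and fixO from 10300 ± 1950 to 156 ± 3.66 (-6.02 ± 0.37). fbcC fell from 5481 ± 986 to 94.2 ± 1.67 (-5.84 ± 0.15). The alpha-glucoside transport genes aglG and aglF (-5.72 ± 0.17 and -5.52 ± 0.12) fell too, as did the manganese and iron transporter row sitA,sitB,sitC,sitD (-5.46 ± 0.11). pssA, which encodes phosphatidylserine synthase, fell from 115 ± 18 to 73.9 ± 1.97 FPKM (-0.62 ± 0.11, adjusted p = 0.00108).

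Most rows of the lists for energy metabolism and protein synthesis fell, and none of the list calls given here held with the correlation between genes estimated from the data. Counts of list members are given over all genes tested, and the counts adjusted over the list alone were identical unless stated. All 12 rows of NADH dehydrogenase (complex I) fell, with a median log2 change of -2.77 (camera adjusted p = 5.87e-05, adjusted p = 0.525 with an estimated correlation). Among them nuoI fell from 1138 ± 129 to 105 ± 7.18 FPKM. All 8 ATP synthase rows fell (median -3.26, camera adjusted p = 5.97e-04, adjusted p = 0.525 with an estimated correlation), atpG from 1971 ± 258 to 111 ± 5.71. The 10 rows of the tricarboxylic acid cycle (median -2.2, camera adjusted p = 2.36e-04) and the 12 of central sugar metabolism (median -2.61, camera adjusted p = 4.52e-05) fell without exception. Both lists had adjusted p = 0.525 with an estimated correlation. fumC changed by -2.78 ± 0.08 and eno by -3.34 ± 0.11. Of 9 aerobic terminal oxidase rows 8 fell and 1 was not called (camera adjusted p = 0.002, adjusted p = 0.525 with an estimated correlation), cyoB from 4336 ± 764 to 399 ± 13.3. That list held the cox and cyo rows, cydA and cydB for the bd-type oxidase, and the row ctaB,gene:AGRO063. Of 49 ribosomal protein rows, 40 fell, 2 rose and 7 were not called (median -1.83, camera adjusted p = 7.53e-07, adjusted p = 0.528 with an estimated correlation). rplL fell from 10030 ± 1960 to 857 ± 56.1, and rpsU#1 (the first of the rows with that name) rose from 113 ± 28.7 to 940 ± 188. Of 23 rows for cell division and DNA replication 17 fell and 4 rose with 2 not called (camera adjusted p = 0.00757, adjusted p = 0.528 with an estimated correlation). ftsK fell by 3.30 ± 0.09. Of the 12 rows for type VI and type IV secretion and conjugation 9 fell and 3 rose (camera adjusted p = 0.0355, adjusted p = 0.528 with an estimated correlation). impB of the type VI system fell by 3.44 ± 0.13 and the row with trbC rose by 2.40 ± 0.07. Of 8 storage polymer rows 7 fell and 1 rose (camera adjusted p = 0.0355, adjusted p = 0.528 with an estimated correlation). The row phaA,phaC,phaD,phaE,phaF,phaG is in that list by its symbols alone, and whether it serves storage is uncertain. The polyhydroxybutyrate synthesis gene phbA fell by 3.61 ± 0.12, while the glycogen synthase gene glgA rose by 3.32 ± 0.09. In the cbb3 list 4 of 5 rows fell and fixQ was not called (camera adjusted p = 0.0355, adjusted p = 0.525 with an estimated correlation). The lists for sugar nucleotide supply (2 rose, 8 fell, 2 not called, camera adjusted p = 0.113), phosphate and polyphosphate (4 rose, 7 fell, 2 not called, camera adjusted p = 0.514) and oxidative stress defence (5 rose, 2 fell, 1 not called, camera adjusted p = 0.22) were not called. The catalase gene katA rose by 3.02 ± 0.09. The nitrogen assimilation list was split, with 13 rows higher, 13 lower and 4 not called (median -0.109 although camera gave the direction as up, camera adjusted p = 0.514). Heme biosynthesis had 1 higher, 6 lower and 1 not called (camera adjusted p = 0.0503, and 0.037 when camera used ranks). The ribosomal and transfer RNA list, which holds rrf and tRNA rows, had 2 higher, 1 lower and 12 not called of 15 tested (camera adjusted p = 0.977). Of its 26 rows the others were too low to be tested, and the list does not measure RNA integrity.

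Over all rows, limma called 3547 of 4664 in the wild-type phase comparison, 1745 higher and 1802 lower in the curdlan phase, of which 1112 and 1074 differed at least 2-fold. Some rows were listed at exactly 0 in single libraries, which can be a failed estimate, so their values are given per library. fixQ stood at 87528 and 92236 FPKM in the growth phase and at 2156 and 1269 in the curdlan phase of the wild type. tRNA#23 was listed at 0 in both growth-phase libraries and at 11582 and 25993 at 24 h, ar7 at 0 and 1088 against 14260 and 19813, ar35#1 at 0 and 856 against 5683 and 8960, and Atu_At1 at 0 and 11544 against 173204 and 157950. The replicates of aglE,gene:AGRO_2746, never listed at 0, also lay far apart, at 95988 and 65822 FPKM in the growth phase and at 2703 and 15.5 in the curdlan phase. Its call (-8.55, adjusted p = 0.0248) was lost with only the groups compared in the fit (adjusted p = 0.0827), without curdlan-phase replicate 2 (-4.88, adjusted p = 0.165) and without growth-phase replicate 1 (adjusted p = 0.0908) or 2 (adjusted p = 0.0746).

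The same transition in the mutant tested which of these changes occurred with fnrN mutated. crdS again rose, from 15.7 ± 0.809 to 3433 ± 56.3 FPKM (7.68 ± 0.21, adjusted p = 3.69e-08). thiC went from 14.8 ± 2.4 to 1745 ± 15.8 (6.8 ± 0.10) and exbB from 18.8 ± 2.46 to 615 ± 14.3 (4.96 ± 0.13). Some cbb3 rows rose in the mutant where they had fallen in the wild type: fixG,fixH,fixI,fixS, for assembly of the oxidase, rose from 38.8 ± 26 to 286 ± 7.72 (3.02 ± 0.39, adjusted p = 1.64e-04) and fixP from 26.7 ± 0.441 to 68.6 ± 2.18 (1.33 ± 0.20). fixN rose from 4.35 ± 0.122 to 14.3 ± 2.11 (1.51 ± 0.40, adjusted p = 0.00891), a call lost without curdlan-phase replicate 1 (1.37, adjusted p = 0.0563), and fixO had 9.13 ± 0.583 and 12.6 ± 3.31 (adjusted p = 0.347). The row with trbC rose from 24.5 ± 2.13 to 2267 ± 16.3 FPKM (6.48 ± 0.07) and the formate dehydrogenase gene fdhA fell from 1668 ± 165 to 24.6 ± 2.06 (-6.03 ± 0.13). aglK, aglG and aglF fell by 5.65 ± 0.14, 5.64 ± 0.17 and 5.57 ± 0.12, and the electron transfer flavoprotein row etfA#4 by 5.33 ± 0.14. The tRNA#17 row was listed at 8876 and 11710 FPKM in the mutant curdlan phase under normoxia and at 0 in the other 10 libraries.

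Of the ribosomal protein rows in the mutant, 40 again fell and 2 rose (camera adjusted p = 2.69e-08, adjusted p = 0.522 with an estimated correlation). All 12 of complex I fell (camera adjusted p = 7.34e-05), as did all 10 of the tricarboxylic acid cycle (camera adjusted p = 8.82e-05). Both lists had adjusted p = 0.498 with an estimated correlation. In addition, 11 of central sugar metabolism fell and talB rose (camera adjusted p = 1.59e-04, adjusted p = 0.522 with an estimated correlation). Falls were also called for 8 of 9 aerobic terminal oxidase rows (camera adjusted p = 1.61e-04) and 7 of 8 ATP synthase rows (camera adjusted p = 0.0013). These had adjusted p = 0.498 and 0.522 with an estimated correlation. cydB and cydA, for the bd-type oxidase, fell by 4.47 ± 0.11 and 3.90 ± 0.11. Chaperones and proteases had 16 rows lower, 2 higher and 3 not called (median -1.77, camera adjusted p = 8.82e-05, adjusted p = 0.522 with an estimated correlation). groEL went from 33020 ± 4140 to 872 ± 20.6 FPKM. In the wild type that list had 13 rows lower and 8 higher (camera adjusted p = 0.254). Its difference between the strains was called, with 15 rows lower, 2 higher and 4 not called (camera adjusted p = 1.32e-06, adjusted p = 0.713 with an estimated correlation). For flagella, motility and chemotaxis 20 rows rose, 3 fell and 5 were not called (22 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.498 with an estimated correlation). cheD rose by 1.87 ± 0.12 and flgL by 1.84 ± 0.12, while the flagellin gene flaB fell by 1.63 ± 0.16. In the wild type the flagellar list had 16 rows higher, 4 lower and 8 not called (camera adjusted p = 0.064). Its difference between the strains was not called, with 10 rows higher, 3 lower and 15 not called (camera adjusted p = 0.524). A further 3 lists had camera adjusted p = 0.0475: storage polymers (2 rose, 6 fell), iron uptake and storage (4 rose, 3 not called, exbB among them) and the secretion and conjugation list (3 rose, 9 fell). They had adjusted p = 0.522, 0.498 and 0.659 with an estimated correlation. In the wild type the iron list had 4 rows higher, 2 lower and 1 not called (camera adjusted p = 0.232), and its difference between the strains was not called (camera adjusted p = 0.608). The calls of the 3 lists in the mutant were lost with each library rescaled by median ratios (adjusted p = 0.0565) and with rows listed at 0 left out (adjusted p = 0.0531). Over all rows 3501 were called in the mutant, 1866 higher and 1635 lower, of which 1161 and 927 differed at least 2-fold, with a median log2 change of 0.12 over all rows tested.

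Across the 4664 rows, the phase responses of the strains had a Pearson correlation of 0.603 and a Spearman correlation of 0.767, and 0.834 and 0.831 over the 4308 rows never listed at 0. Genes are not independent replicates, and the strains shared no library. Of the rows called higher, 1444 were shared, where independent lists of these sizes would share 698. Of those called lower, 1361 were shared, where independent lists would share 632. These reference numbers are not a chance level, since both comparisons used the same estimate of each row's spread. Of the rows called higher in the wild type 96 were called lower in the mutant, and of those called lower 152 were called higher. The test of the difference itself called 1990 rows, 1238 with a higher and 752 with a lower log2 change in the mutant than in the wild type. After rescaling the libraries by median ratios these were 1195 and 984, so that the share with a higher change went from 62.2 to 54.8%. The median difference over all rows was 0.148 as deposited and 0.0431 after rescaling. fixG,fixH,fixI,fixS (7.41 ± 0.55), fixN (7.19 ± 0.56), fixP (6.63 ± 0.28) and fixO (6.42 ± 0.52) had higher log2 changes in the mutant, with adjusted p of 3.83e-05, 4.9e-05, 3.76e-06 and 5.54e-05. hemN#2, which encodes an oxygen-independent coproporphyrinogen oxidase of heme synthesis, differed by 5.57 ± 0.17. The row hemN#1 of the same name differed in the other direction, by -0.695 ± 0.204 (adjusted p = 0.0274). The difference was -4.14 ± 0.20 for nrtB, -3.34 ± 0.13 for amtB, -3.15 ± 0.35 for ntrA and -2.63 ± 0.10 for nirB. crdS showed a difference of -0.16 ± 0.29 (adjusted p = 0.708), which became a called -0.54 without wild-type growth-phase replicate 2 (adjusted p = 0.00218).

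**Figure D2:**
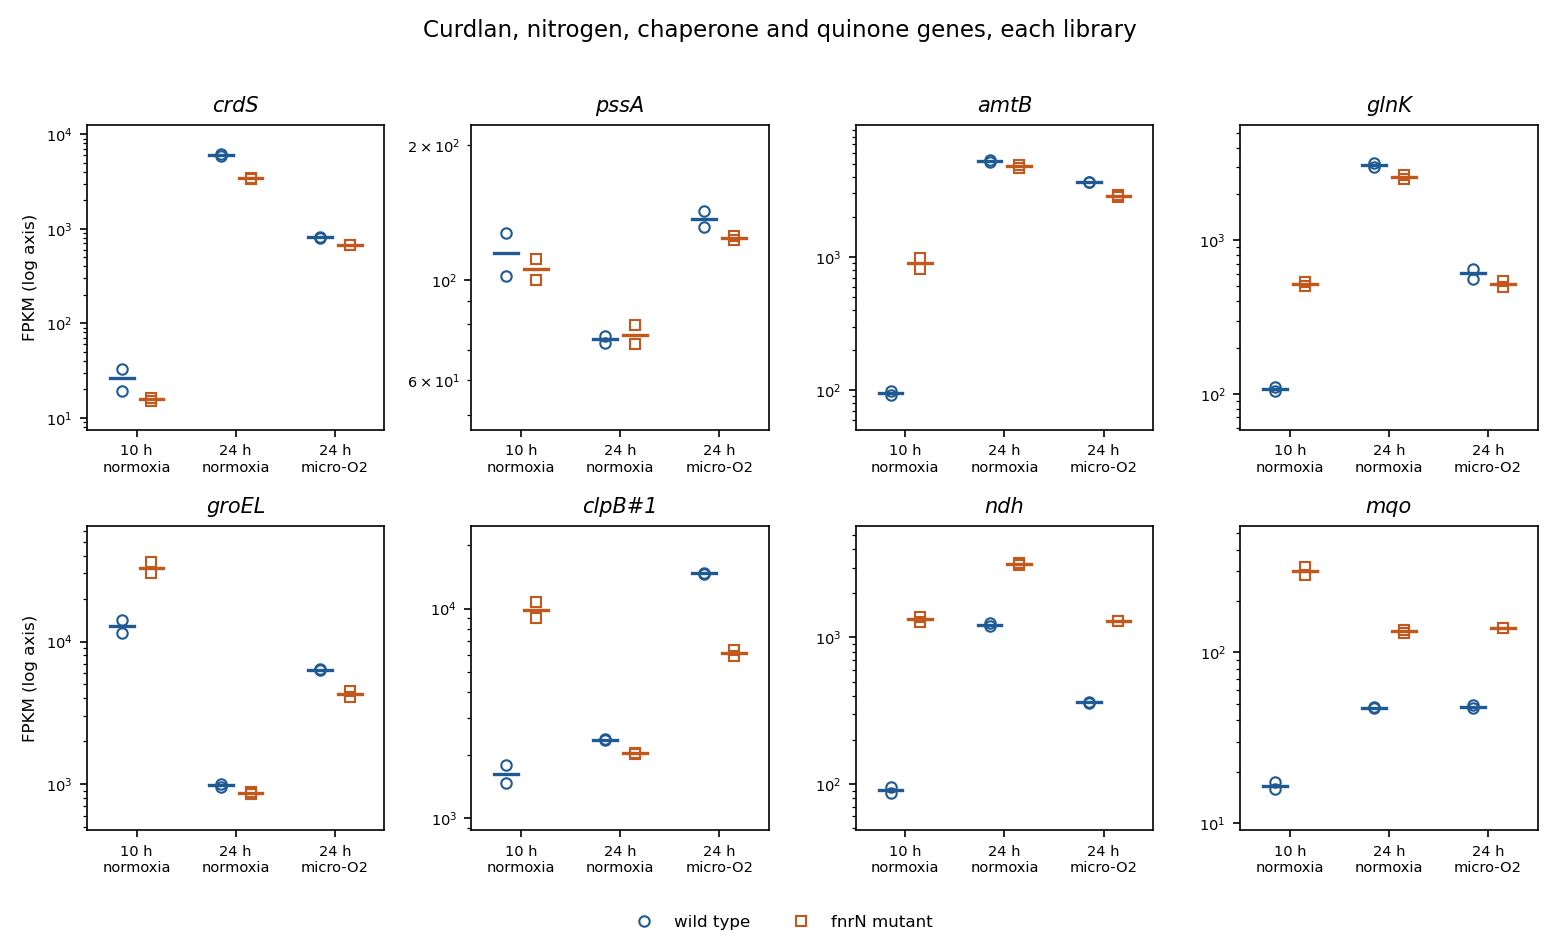
FPKM on a log axis of 8 rows in each library (points) with the group mean (bars), for the wild type (blue circles) and the mutant (orange squares) in the 3 conditions. crdS stood at a mean of 6003 in the wild type and 3433 in the mutant at 24 h under normoxia, and at 809 and 674 with micro-oxygen, while ndh was higher in the mutant in all 3 conditions.

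The second comparison asked how the wild type differed at 24 h between micro-oxygen treatment and normoxia. crdS fell from 6003 ± 271 to 809 ± 10.8 FPKM (-2.89 ± 0.21, adjusted p = 1.5e-05), while pssA rose from 73.9 ± 1.97 to 137 ± 8.15 (0.88 ± 0.11, adjusted p = 2.76e-04). The chaperonin genes groEL and groES rose, groEL from 982 ± 27.7 to 6357 ± 34.8 (2.69 ± 0.13, adjusted p = 2.94e-06) and groES from 963 ± 52.2 to 7419 ± 178 (2.95 ± 0.15). The disaggregase gene clpB#1 rose from 2373 ± 13.3 to 14720 ± 93 (2.63 ± 0.12), and hslV, of the HslUV protease, from 519 ± 5.15 to 3087 ± 76.2 (2.57 ± 0.10). Of the cbb3 genes, fixN rose from 195 ± 7.61 to 616 ± 12 (1.66 ± 0.40, adjusted p = 0.00819) and fixO from 156 ± 3.66 to 561 ± 27.1 (1.84 ± 0.37, adjusted p = 0.00331). fixP rose from 249 ± 1.68 to 626 ± 14.8 (1.33 ± 0.20, adjusted p = 7.44e-04). In the wild-type growth phase the same 3 genes had stood at 10100 ± 1720, 10300 ± 1950 and 9910 ± 1370 FPKM. fixG,fixH,fixI,fixS rose from 459 ± 17.7 to 1322 ± 228 (1.52 ± 0.39, adjusted p = 0.0108), a call lost without normoxia replicate 2 (adjusted p = 0.0525) or micro-oxygen replicate 2 (adjusted p = 0.0664). fixK, a regulator of the same family as fnrN, had 37.4 ± 0.808 and 47.4 ± 0.472 FPKM (0.33 ± 0.10, adjusted p = 0.0212). That call was lost without normoxia replicate 1 (adjusted p = 0.0916) or 2 (0.0618) and without micro-oxygen replicate 1 (0.0695) or 2 (0.0818). kdgR#2 (58.2 ± 7.87 to 653 ± 24.6) and pecM (23.7 ± 0.343 to 197 ± 3.92) rose by 3.47 ± 0.11 and 3.0 ± 0.08. The regulator gene nolR fell by 2.66 ± 0.07, usg by 2.45 ± 0.13 and glnK by 2.35 ± 0.09 on the log2 scale.

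Of the 21 rows for chaperones and proteases, 19 rose, 1 (dnaJ#4) fell and 1 was not called with micro-oxygen in the wild type (median 1.54, camera adjusted p = 2.28e-07, adjusted p = 0.773 with an estimated correlation). The polysaccharide list, which holds succinoglycan, cellulose and beta-glucan genes other than those for curdlan, had 21 of 29 rows lower, 1 higher and 7 not called (median -0.557, camera adjusted p = 2.16e-04, adjusted p = 0.773 with an estimated correlation). exoW fell from 254 ± 18.2 to 120 ± 3.82 FPKM. Nitrogen assimilation had 19 of 30 rows lower, 4 higher and 7 not called (median -0.682, camera adjusted p = 0.0031, adjusted p = 0.773 with an estimated correlation). nirB fell by 1.92 ± 0.07. For cell division and DNA replication 17 of 23 rows fell, 2 rose and 4 were not called (18 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.836 with an estimated correlation). Of the ATP synthase rows 7 rose and 1 was not called (median 0.512, camera adjusted p = 0.0118, adjusted p = 0.773 with an estimated correlation), atpG from 111 ± 5.71 to 212 ± 17.4. In the secretion and conjugation list 9 rows rose, 8 of them imp rows of the type VI system and the other vgrG#1, and 3 fell (camera adjusted p = 0.0427, adjusted p = 0.836 with an estimated correlation). That call was lost with rows listed at 0 left out (adjusted p = 0.0504). The tricarboxylic acid cycle list, with 6 rows higher and 4 not called, was called only after rescaling the libraries (camera adjusted p = 0.122 as deposited, 0.0407 rescaled). The cbb3 list had 4 rows higher and 1 not called (camera adjusted p = 0.122). katA fell by 1.98 ± 0.09 and bfr,gene:AGRO-1048, for an iron storage protein, by 1.94 ± 0.14, whereas trxB, for thioredoxin reductase, rose by 2.30 ± 0.09 and the iron regulator gene irr by 1.32 ± 0.11. Over all rows 2699 were called, 1263 higher and 1436 lower, of which 439 and 420 differed at least 2-fold. After rescaling 1447 were higher and 1426 lower, so the excess of lower rows was lost. RNaseP_bact_a, the RNA of ribonuclease P, was listed at 0 in all 4 micro-oxygen libraries and at 197677 to 642913 FPKM in the other 8. tRNA#19 was listed at 17862 and 18554 FPKM in the wild type and at 40276 and 28315 in the mutant with micro-oxygen, and at 0 in the other 8 libraries.

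In the mutant, crdS fell from 3433 ± 56.3 to 674 ± 1.55 FPKM with micro-oxygen (-2.35 ± 0.21, adjusted p = 6.58e-05) and pssA rose from 75.7 ± 5.1 to 124 ± 1.46 (0.71 ± 0.11, adjusted p = 0.0012). groEL rose from 872 ± 20.6 to 4306 ± 310 (2.30 ± 0.13), groES from 1209 ± 79.6 to 4919 ± 164 (2.02 ± 0.15). Rises were also called for pecM, from 61.1 ± 3.41 to 516 ± 23.1 (3.06 ± 0.08), kdgR#2 from 210 ± 8.33 to 831 ± 5.5 (1.98 ± 0.11) and mexE, for a subunit of an efflux pump, from 81.2 ± 2.22 to 420 ± 20.4 (2.35 ± 0.08). usg fell by 3.68 ± 0.13, nolR by 2.38 ± 0.07, the cold-shock gene row cspA#5 by 2.33 ± 0.19, glnK by 2.32 ± 0.09 and mucS by 2.27 ± 0.13. Of the cbb3 rows, fixP had 68.6 ± 2.18 and 69.9 ± 23.7 FPKM (-0.01 ± 0.20, adjusted p = 0.974) and fixG,fixH,fixI,fixS 286 ± 7.72 and 353 ± 27.1 (adjusted p = 0.553). Without micro-oxygen replicate 1, fixP was called lower (-0.36, adjusted p = 0.0434). fixN had 14.3 ± 2.11 and 34.7 ± 23.7 (1.04 ± 0.40, adjusted p = 0.0621), with adjusted p = 0.0448 after rescaling, 0.0355 with rows listed at 0 left out, and a change of 1.78 without micro-oxygen replicate 2 (adjusted p = 5.12e-04). fixO rose from 12.6 ± 3.31 to 36.8 ± 21.9 (1.37 ± 0.37, adjusted p = 0.0161), a call lost without normoxia replicate 2 (1.12, adjusted p = 0.1) and when only the groups compared entered the fit (adjusted p = 0.146). The change was 0.74 without micro-oxygen replicate 1 (adjusted p = 0.0456). fixK rose from 34.6 ± 2.31 to 53.2 ± 8.08 (0.60 ± 0.10, adjusted p = 0.00165), a call lost when only the groups compared entered the fit (adjusted p = 0.0557).

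With micro-oxygen in the mutant, chaperones and proteases had 17 rows higher, 1 lower and 3 not called (median 0.915, camera adjusted p = 4.55e-06, adjusted p = 0.98 with an estimated correlation). The other polysaccharide genes had 15 lower, 1 higher and 13 not called (camera adjusted p = 7.8e-04, adjusted p = 0.98 with an estimated correlation). exoY,gene:AGRO_4451 fell from 2515 ± 19.8 to 878 ± 76.2 FPKM. Nitrogen assimilation had 19 lower, 3 higher and 8 not called (20 lower and 4 higher adjusted over the list alone, camera adjusted p = 0.00412, adjusted p = 0.98 with an estimated correlation). Cell division had 14 lower, 3 higher and 6 not called (camera adjusted p = 0.0268, adjusted p = 0.98 with an estimated correlation). The cell-cycle regulator gene ctrA fell by 1.28 ± 0.10. ATP synthase had 3 rows higher and 5 not called (camera adjusted p = 0.128), and the secretion and conjugation list 9 higher and 3 lower (camera adjusted p = 0.0949). Neither list was called for the difference between the strains (camera adjusted p = 0.17 and 0.194). Over all rows 2325 were called, 1128 higher and 1197 lower, of which 211 and 364 differed at least 2-fold. After rescaling 1424 were higher and 1171 lower, so the balance of the calls depended on the scaling. The micro-oxygen responses of the strains had a Pearson correlation of 0.273 and a Spearman correlation of 0.686 across rows, and 0.775 and 0.78 without rows listed at 0. Of the rows called higher 825 were shared (305 for independent lists), and of those called lower 993 (369 for independent lists). Of the rows called higher in the wild type 28 were called lower in the mutant, and of those called lower 46 were called higher. The difference of the responses was called for 785 rows, 396 with a higher and 389 with a lower log2 change in the mutant. These were 1202 after rescaling and 1198 with only the groups compared. They were 455 and 430 without wild-type normoxia replicate 1 or 2, 451 without wild-type micro-oxygen replicate 1, 419 without mutant normoxia replicate 1, and 520 and 485 without mutant micro-oxygen replicate 1 or 2. For 9 ribosomal protein rows the change was lower in the mutant and 40 were not called (median difference -0.452, camera adjusted p = 1.98e-06, adjusted p = 0.926 with an estimated correlation). For chaperones and proteases 10 were lower, 2 higher and 9 not called (12 lower and 2 higher adjusted over the list alone, camera adjusted p = 4.62e-05, adjusted p = 0.926 with an estimated correlation). clpB#1 showed a difference of -1.05 ± 0.16 (adjusted p = 0.00584), while that of clpB#2 was not called (-0.27 ± 0.115, adjusted p = 0.151). The small heat-shock protein gene hspL showed a difference of -1.56 ± 0.22 (adjusted p = 0.00406). hspL stood at 10800 ± 321 and 32680 ± 212 FPKM in the wild type and 11470 ± 57.3 and 11820 ± 651 in the mutant. The difference for crdS was 0.54 ± 0.29 (adjusted p = 0.258, and 0.00342 when only the groups compared entered the fit). For fnrN it was 0.52 ± 0.15 (adjusted p = 0.0511, and 0.00671 after rescaling, 0.0112 with only the groups compared, 0.0409 with rows listed at 0 left out, 0.0471 with robust eBayes and 0.0499 at a mean FPKM of at least 10).

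**Figure D3:**
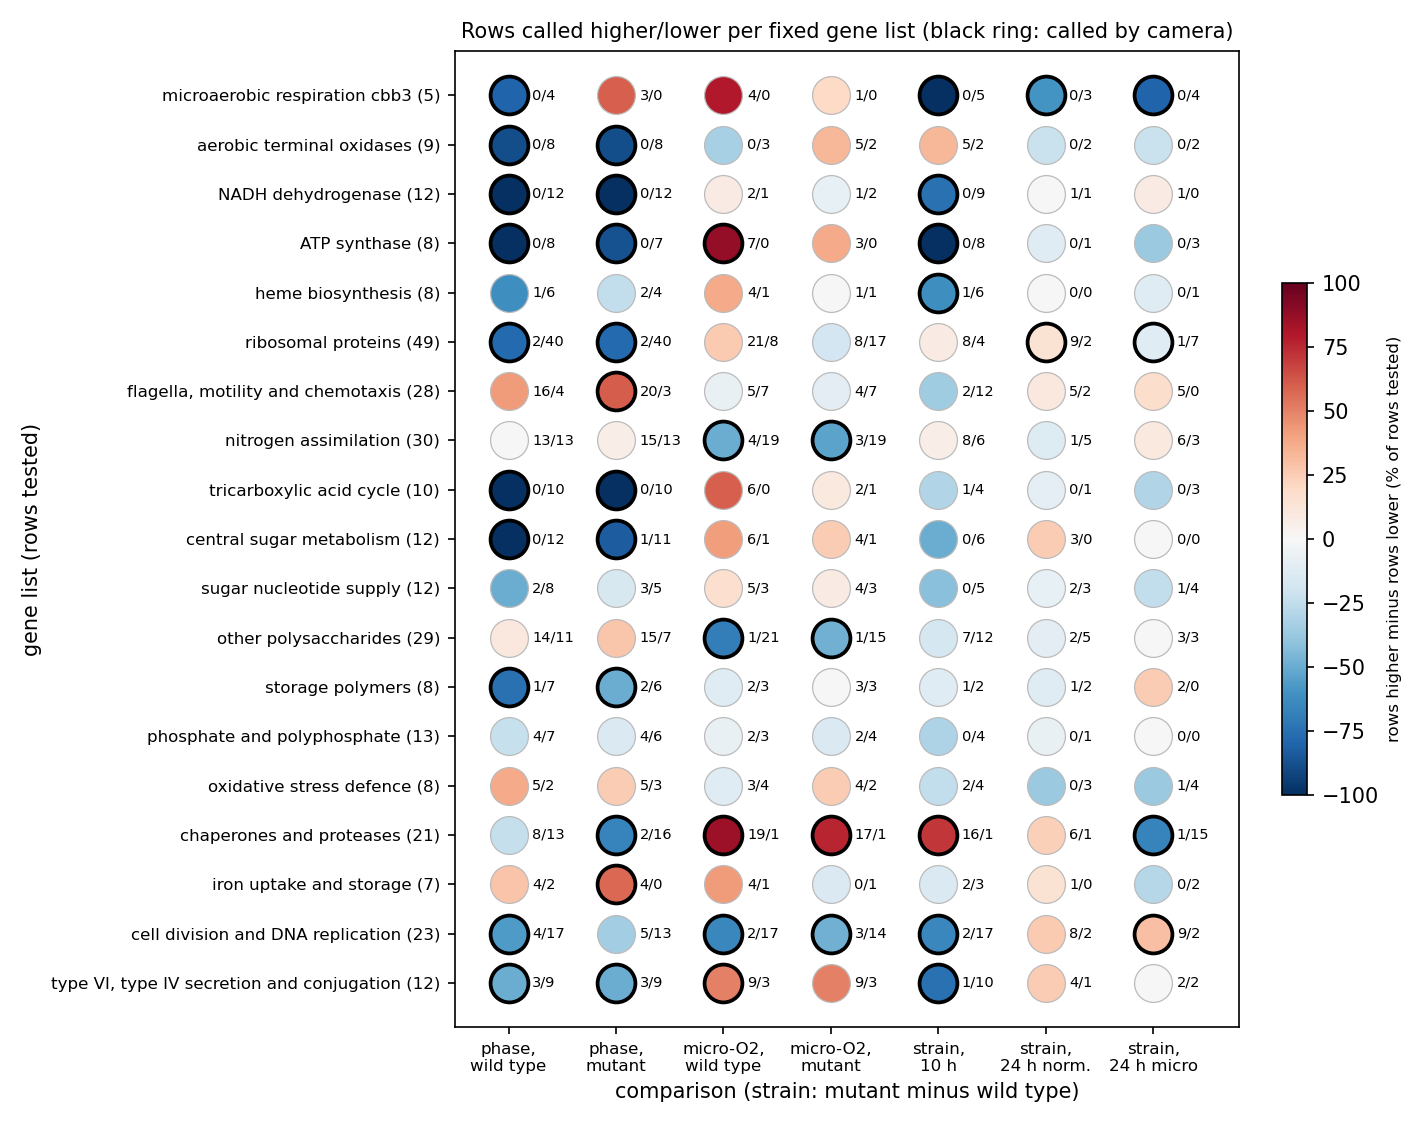
Number of rows called higher and lower (text) in each gene list tested by camera, except ribosomal and transfer RNA. All comparisons are shown except the differences between strains of the phase and micro-oxygen responses. Colour gives rows higher minus rows lower as a percentage of those tested. A black ring marks a list called by camera, a call that no list kept with an estimated correlation. Chaperones and proteases had 19 rows higher and 1 lower with micro-oxygen in the wild type, and 16 higher and 1 lower in the mutant at 10 h.

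The third comparison set the mutant against the wild type in each condition, starting with the growth phase. Several cbb3 rows were far lower in the mutant: fixN stood at 4.35 ± 0.122 against 10100 ± 1720 FPKM in the wild type (-10.87 ± 0.40, adjusted p = 7.05e-07), and fixO at 9.13 ± 0.583 against 10300 ± 1950 (-9.98 ± 0.37). fixP stood at 26.7 ± 0.441 against 9910 ± 1370 (-8.48 ± 0.20) and fixG,fixH,fixI,fixS at 38.8 ± 26 against 9604 ± 139 (-8.09 ± 0.39). sinR, which in Agrobacterium encodes another FNR-type regulator, was at 5.83 ± 1.97 against 8533 ± 747 (-10.31 ± 0.44), adhP, an alcohol dehydrogenase gene, at 232 ± 17.5 against 13580 ± 1800 (-5.86 ± 0.17), and hemN#2 at 25.3 ± 3.54 against 1269 ± 179 (-5.59 ± 0.12). Higher in the mutant were mqo, for malate:quinone oxidoreductase (300 ± 24.5 against 16.6 ± 1.11, 4.10 ± 0.07, adjusted p = 6.74e-08) and ndh, for the NADH dehydrogenase that does not pump protons (1332 ± 80.3 against 91.2 ± 6.52, 3.85 ± 0.07). The same was true of fdhF,gene:AGRO_5272 (154 ± 13.6 against 12.6 ± 0.512, 3.51 ± 0.10) and nadC, of NAD synthesis (104 ± 5 against 8.35 ± 1.14, 3.50 ± 0.11). amtB was also higher, at 895 ± 122 against 95.6 ± 3.95 (3.21 ± 0.09), as was hslU at 2146 ± 196 against 286 ± 38.3 (2.91 ± 0.10). fixQ was listed at 129 and 0 in the mutant against 87528 and 92236 in the wild type. fixK had 17.8 ± 0.0449 against 23.2 ± 0.472 FPKM (-0.36 ± 0.10, adjusted p = 0.0158), a call lost after rescaling (-0.27, adjusted p = 0.0644), with only the groups compared (adjusted p = 0.0557), and without wild-type replicate 2 (adjusted p = 0.0621), mutant replicate 1 (0.0623) or mutant replicate 2 (0.0567). crdS had 15.7 ± 0.809 against 26.1 ± 10 (-0.65 ± 0.21, adjusted p = 0.0309). That call was lost after rescaling (-0.55, adjusted p = 0.0854), with only the groups compared (adjusted p = 0.223), and without mutant replicate 1 (-0.60, adjusted p = 0.122) or 2 (-0.70, adjusted p = 0.078). The change was -1.03 without wild-type replicate 1 (adjusted p = 4.67e-05) and -0.26 without wild-type replicate 2 (adjusted p = 0.0125). pssA had 106 ± 7.91 and 115 ± 18 (adjusted p = 0.458).

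Chaperones and proteases had 16 of 21 rows higher in the mutant growth phase, 1 lower and 4 not called (17 higher and 1 lower adjusted over the list alone, median 1.3, camera adjusted p = 3.37e-08, adjusted p = 0.948 with an estimated correlation). Among them, groEL stood at 33020 ± 4140 against 12840 ± 2010 FPKM, clpB#1 at 9884 ± 1160 against 1637 ± 227, and dnaK at 14590 ± 1320 against 3311 ± 396. All 5 cbb3 rows were lower (median -9.98, camera adjusted p = 0.00404), as were all 8 ATP synthase rows (median -0.574, camera adjusted p = 0.0373). These had adjusted p = 0.787 and 0.948 with an estimated correlation. Of complex I, 9 of 12 rows were lower and 3 not called (median -0.682, camera adjusted p = 0.042, adjusted p = 0.948 with an estimated correlation), a call lost with rows listed at 0 left out (adjusted p = 0.0513). For heme biosynthesis 6 rows were lower, 1 higher and 1 not called (camera adjusted p = 0.0332, adjusted p = 0.948 with an estimated correlation), with hemB at 255 ± 18.6 against 817 ± 66.8 FPKM. Cell division and DNA replication had 17 lower, 2 higher and 4 not called (18 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.00831, adjusted p = 0.948 with an estimated correlation). ccrM stood at 432 ± 25.7 against 1051 ± 104. The secretion and conjugation list had 10 lower, 1 higher and 1 not called (camera adjusted p = 0.0281, adjusted p = 0.948 with an estimated correlation). The row holding trbC stood at 24.5 ± 2.13 against 437 ± 32.8. The ribosomal protein list, with 8 rows higher, 4 lower and 37 not called (2 higher and 0 lower adjusted over the list alone), was called after rescaling (camera adjusted p = 0.0723 as deposited, 0.0144 rescaled) or with camera on ranks (0.022). The sigma factor gene rpoH, which is in the list of general stress regulators, was higher in the mutant by 1.98 ± 0.09 and dksA lower (-0.98 ± 0.10). That list, with 2 rows, was too short for camera. Over all rows 2485 were called, 815 higher and 1670 lower, and 1055 and 1519 after rescaling, with median log2 changes over all rows of -0.151 as deposited and -0.0531 rescaled. With only the groups compared in the fit 1434 were called. At least 2-fold differences were called for 284 rows higher and 359 lower.

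At 24 h under normoxia, sinR (13.7 ± 0.476 against 948 ± 6.6 FPKM, -6.01 ± 0.44, adjusted p = 1.06e-04), fixN (14.3 ± 2.11 against 195 ± 7.61, -3.68 ± 0.40, adjusted p = 5.75e-04), and fixO (12.6 ± 3.31 against 156 ± 3.66, -3.55 ± 0.37) were again lower in the mutant. The same held for fixP (68.6 ± 2.18 against 249 ± 1.68, -1.85 ± 0.20) and adhP (62.4 ± 1.98 against 459 ± 9.47, -2.86 ± 0.17). The nitrate transport gene nrtB (83.7 ± 4.56 against 231 ± 14.9 FPKM, -1.45 ± 0.14) and nirB (-1.36 ± 0.07) were also lower. kdgR#2 (210 ± 8.33 against 58.2 ± 7.87, 1.84 ± 0.11), the branched-chain amino acid gene ilvC (644 ± 7.36 against 222 ± 4.9, 1.53 ± 0.10), and lpxC of lipid A synthesis (1801 ± 3.63 against 664 ± 24.8, 1.44 ± 0.11) were higher, as were mqo (1.47 ± 0.07), ndh (1.37 ± 0.07) and pecM (1.33 ± 0.08). crdS was listed at 3433 ± 56.3 in the mutant and 6003 ± 271 in the wild type (-0.81 ± 0.21, adjusted p = 0.0256). Its call was lost without wild-type replicate 1 (adjusted p = 0.116) or 2 (0.086) and without mutant replicate 1 (0.101) or 2 (0.109). fixG,fixH,fixI,fixS had 286 ± 7.72 and 459 ± 17.7 (-0.68 ± 0.39, adjusted p = 0.24, and 0.0106 with only the groups compared in the fit). pssA had 75.7 ± 5.1 and 73.9 ± 1.97 (adjusted p = 0.871), and fixK 34.6 ± 2.31 and 37.4 ± 0.808 (adjusted p = 0.452). In the cbb3 list 3 rows were lower and 2 not called (median -3.55, camera adjusted p = 0.0154), and 9 ribosomal protein rows were higher, 2 lower and 38 not called (median 0.227, camera adjusted p = 0.0154), with adjusted p = 0.897 with an estimated correlation for both. rplJ stood at 1645 ± 96.1 against 1011 ± 22.3. Over all rows 1245 were called, 563 higher and 682 lower, of which 99 and 72 differed at least 2-fold. The calls numbered 731 and 744 without wild-type replicate 1 or 2, and 748 and 792 without mutant replicate 1 or 2.

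With micro-oxygen at 24 h, sinR (31.5 ± 22.7 against 1384 ± 0.325 FPKM, -5.62 ± 0.44, adjusted p = 2.09e-04), fixN (34.7 ± 23.7 against 616 ± 12, -4.29 ± 0.40, adjusted p = 4.13e-04), fixO (36.8 ± 21.9 against 561 ± 27.1, -4.03 ± 0.37), and fixP (69.9 ± 23.7 against 626 ± 14.8, -3.19 ± 0.20) were lower in the mutant. So were adhP (116 ± 31.3 against 1128 ± 9.69, -3.29 ± 0.17) and hemN#2 (52.5 ± 4.09 against 215 ± 10.2, -2.01 ± 0.12). The isocitrate lyase gene aceA was lower as well (27.8 ± 3.09 against 105 ± 4.56, -1.88 ± 0.12). fixG,fixH,fixI,fixS stood at 353 ± 27.1 against 1322 ± 228 (-1.89 ± 0.39, adjusted p = 0.0112), a call lost without wild-type replicate 2 (adjusted p = 0.0698) and without mutant replicate 1 (0.053) or 2 (0.0682). ndh (1295 ± 12.3 against 360 ± 0.964, 1.84 ± 0.07), mqo (139 ± 0.356 against 48.1 ± 1.16, 1.51 ± 0.07), pecM (1.39 ± 0.08), fdhF,gene:AGRO_5272 (1.39 ± 0.10) and nadC (1.09 ± 0.11) were higher. crdS had 674 ± 1.55 and 809 ± 10.8 (-0.26 ± 0.21, adjusted p = 0.41, and 0.0198 with only the groups compared) and pssA 124 ± 1.46 and 137 ± 8.15 (adjusted p = 0.405). fixK had 53.2 ± 8.08 and 47.4 ± 0.472 (adjusted p = 0.311, and 0.0462 without mutant replicate 2 at a change of 0.31). In the cbb3 list 4 rows were lower and 1 not called (camera adjusted p = 5.45e-04, adjusted p = 0.475 with an estimated correlation). Chaperones and proteases had 15 rows lower in the mutant, 1 higher and 5 not called (15 lower and 3 higher adjusted over the list alone, median -0.506, camera adjusted p = 5.45e-04, adjusted p = 0.933 with an estimated correlation). clpB#1 stood at 6132 ± 266 against 14720 ± 93 and dnaK at 8768 ± 475 against 17690 ± 187 FPKM. Ribosomal proteins had 7 rows lower, 1 higher and 41 not called (camera adjusted p = 0.00179), and cell division 9 higher, 2 lower and 12 not called (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00248). Both lists had adjusted p = 0.933 with an estimated correlation. Over all rows 1120 were called, 502 higher and 618 lower, of which 54 and 87 differed at least 2-fold. The calls numbered 664 and 701 without wild-type replicate 1 or 2, and 714 and 659 without mutant replicate 1 or 2.

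Lower in the mutant in all 3 conditions were 165 rows, where independent lists of these sizes would share 32.4, and higher in all 3 were 37, where 10.6 would be shared. Of these, 12 and 4 differed at least 2-fold in each condition. The 6 with a gene symbol among the 12 were sinR, fixN, fixO, fixP, adhP and ccmC, a gene for cytochrome c maturation, whose log2 changes were -2.29, -1.01 and -1.05. The 3 with a symbol among the 4 were ndh, mqo and nadC. Pairs of conditions differed in how many calls they shared: growth phase and normoxia at 24 h had 373 lower rows in common (244 for independent lists) and 141 higher (98.4), growth phase and micro-oxygen 250 (221) and 82 (87.7), and the conditions at 24 h 245 (90.4) and 182 (60.6).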

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

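The tests chosen only after the result was seen were camera on ranks, both intervals of the set of FnrN-dependent genes, and those of a difference in scale, of wild-type cells or RNA, of a part of fnrN left in the mutant and of a single library out of place.

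The results in this part are those where the strains differed in their response by the test of the difference itself, in limma. For the micro-oxygen response the difference was called for 785 rows, among them 73 of the 255 named genes, of which some are given singly. The calls numbered 1202 after rescaling, 1198 with only the groups compared, 455 and 430 without wild-type normoxia replicate 1 or 2, 451 without wild-type micro-oxygen replicate 1, 419 without mutant normoxia replicate 1, and 520 and 485 without mutant micro-oxygen replicate 1 or 2. The difference (mutant minus wild type, log2) was -1.34 for fixP, a call lost without normoxia replicate 1 (adjusted p = 0.0605) or 2 (0.0614) or micro-oxygen replicate 1 (0.0633) or 2 (0.0535) of the wild type, and without normoxia replicate 1 (0.0594) or 2 (0.0613) of the mutant. It was 1.5 for cy2, 1.25 for cydC,cydD, whose products are needed for assembly of cytochrome bd, and 1.18 for the sulfur assimilation row cysN,gene:AGRO496. For alpha_tmRNA it was 1.38 and for cysE#1, a serine acetyltransferase row, 1.32, and both calls (adjusted p = 0.025 and 0.0229) were lost without each of the 8 libraries in turn. It was -1.99 for hemN#2, -1.97 for the aldehyde dehydrogenase gene aldA, -1.71 for the acyl carrier protein row acpP#2 and -1.56 for hspL. Both the micro-oxygen and the phase difference were called for tRNA#17, whose highest library, in the mutant at 24 h under normoxia, held 11709.6 FPKM and which was listed at 0 in all other groups. Among the lists, the difference was called for ribosomal proteins (camera adjusted p = 1.98e-06) and for chaperones and proteases (camera adjusted p = 4.62e-05), both with adjusted p = 0.926 with an estimated correlation.

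For the phase response the difference was called for 1990 rows, among them 159 named genes. It was 7.41 for fixG,fixH,fixI,fixS, 7.19 for fixN, 6.63 for fixP, 6.42 for fixO and -1.18 for fnrN. It was -4.14 for nrtB and -3.51 for nrtC#2, of nitrate transport, -3.34 for amtB, -3.15 for ntrA and -2.996 for Atu_C7, the last lost with only the groups compared in the fit (adjusted p = 0.053) and without mutant growth-phase replicate 1 (adjusted p = 0.0509). The cbb3 list had 4 rows with a higher change in the mutant and 1 not called, the secretion and conjugation list 7 and 5, and cell division 15 with 3 lower and 5 not called (16 and 3 adjusted over the list alone), each with camera adjusted p = 0.00689 and adjusted p = 0.713 with an estimated correlation. Chaperones and proteases had 15 rows with a lower change, 2 with a higher one and 4 not called (camera adjusted p = 1.32e-06, adjusted p = 0.713 with an estimated correlation). Complex I had 10 higher, 1 lower and 1 not called, ATP synthase 7 higher and 1 not called (8 higher adjusted over the list alone), heme biosynthesis 5 higher, 1 lower and 2 not called, and nitrogen assimilation 9 lower, 3 higher and 18 not called, each with camera adjusted p = 0.0316 and adjusted p = 0.713 with an estimated correlation. Central sugar metabolism had 8 higher, 1 lower and 3 not called (camera adjusted p = 0.0394), and the aerobic terminal oxidases 5 lower and 4 not called (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0464), both with adjusted p = 0.713 with an estimated correlation. The oxidase call was lost after rescaling (adjusted p = 0.0522) and with camera on ranks (0.0976), and that of nitrogen assimilation on ranks (0.0735).

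The genes of the cbb3 oxidase, which serves respiration at low oxygen, stood higher in the wild-type growth phase under labelled normoxia than with micro-oxygen at 24 h. An exchange of these wild-type libraries was argued against, since the growth-phase levels correlated better across genes with mutant growth-phase libraries (mean Spearman 0.875, 0.87 to 0.881 over 4 pairs) than with mutant micro-oxygen libraries (0.694, 0.677 to 0.709), a difference of 0.181. A difference in scale was argued against as the whole cause, since the median log2 difference of the 5 rows was 4.024 as deposited and 3.951 after rescaling (2.797 to 4.581). Over 62 other rows at least 2-fold lower in the mutant at 24 h under normoxia, the median strain effect was -0.6556 at 10 h and -0.7315 with micro-oxygen. The difference was 0.07582 (bootstrap 95% interval -0.1732 to 0.2821). For this interval and the next, rows were resampled and libraries held fixed, so the spread between libraries is left out and rows are treated as independent. The choice of rows at 24 h leaves out genes dependent on fnrN mainly at 10 h. The set therefore cannot decide whether FnrN-dependent genes were more dependent on fnrN at 10 h. Row by row, 40 of the 62 had the lower effect at 10 h, with a median difference of -0.2379 (-0.5121 to -0.1111). Of the 4301 rows never listed at 0 other than fix rows and fnrN, 2637 had it too, with a median of -0.2058. A stronger dependence of FnrN-dependent genes on fnrN at 10 h stays open. An oxygen limitation of the 10 h culture, which was not tested, stays open as well.

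The fnrN row kept a signal in the mutant, at 52.9% of the wild-type level in the growth phase. Wild-type cells or RNA in the mutant libraries were argued against, since fixP, fixO, sinR and fixN held 0.269, 0.0887, 0.0684 and 0.043% of their wild-type levels there. Transcription of a part of fnrN left in the mutant cannot be told apart from other sources, since the table holds 1 value per gene and no positions, and the labels, which write the strain as deltafnrN, do not say how much was removed. The highest group mean of fnrN was 1.19 times the lowest in the mutant and 2.54 times in the wild type.

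In the growth phase more rows were lower than higher in the mutant, 1670 against 815, and 904 against 530 with only the groups compared in the fit. Of the called rows 32.8% were higher as deposited and 41% after rescaling, so the part of a scale difference that rescaling removed was not the whole cause. The median log2 change over all rows was still -0.0531 after rescaling, so a remaining difference in scale was not excluded. A single library out of place was argued against as the whole cause, since the share of higher rows was 39.1% without wild-type replicate 1, 29.3% without wild-type replicate 2, 37.2% without mutant replicate 1 and 28.9% without mutant replicate 2. Leaving out a single library does not test libraries out of place together. Wild-type replicate 1 and mutant replicate 1 had opposite offsets, with a median log2 ratio to the mean of all libraries of 0.106 and -0.106. An effect of the mutation on growth rate stays open and was not tested.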

How the results depend on the processing

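The settings of rows listed at 0 left out, robust eBayes, a log2 change of at least 1 and camera on ranks were chosen after seeing the data. Counts of called rows moved by over 1.5 times under 4 settings. Requiring a log2 change of at least 1, which can only remove calls, left 2186 rows for the wild-type phase change, 2088 for the mutant one, 859 and 575 for micro-oxygen in the wild type and the mutant, 643, 171 and 141 for the strains at 10 h, 24 h normoxia and 24 h micro-oxygen, and 182 and 780 for the differences of the micro-oxygen and phase responses. With only the groups compared in the fit, 1434 rows were called between the strains at 10 h (530 higher, 904 lower) and 1198 for the difference of the micro-oxygen responses (555 higher, 643 lower), and with libraries rescaled by median ratios 1202 for the latter (608 higher, 594 lower). The cause of these moves was not tested. The growth-phase replicates lay further apart than those at 24 h, with median absolute log2 differences of 0.195 and 0.153 against 0.0916 to 0.108. The shared estimate of the spread may thus be too small for comparisons at 10 h and too large for those at 24 h. Leaving out 1 library, which leaves 1 group with a lone sample assumed to vary like the others, gave, in the same order of comparisons, 3314 to 3445, 3254 to 3315, 2321 to 2372, 1848 to 1924, 2028 to 2440, 731 to 792, 659 to 714, 419 to 531 and 1687 to 2123 called rows. These fits hold fewer samples. Of the list tests 56 were called as reported and 0 with an estimated correlation, against 54 after rescaling and 56 on ranks. The Pearson correlation of the strains' responses was 0.834 for phase and 0.775 for micro-oxygen without rows listed at 0 (0.603 and 0.273 with them), and 0.529 and 0.196 at a pseudocount of 0.1. The 630 results on named genes were recomputed under 8634 alternatives. Of these, 8067 kept the side of the threshold, 547 (of 136 results) lost the call and 20 (of 13 results) gained it. The sign reversed in 0 of the results that were called as reported or in the alternative. A change of sign between fits that both lacked a call was counted as kept. Deviations of same-numbered libraries had correlations of -0.0811 to 0.0639 over 15 pairs of groups, and of -0.239 to 0.222 without rows listed at 0. Not every pair was above 0.1, so the numbers were not taken to pair the samples. With a replicate block 3518, 3462, 2610, 2217, 2387, 1104, 977, 644 and 1890 rows and 53 lists were called. Depth is unknown, so the error of low rows and of rows listed at 0 cannot be given.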

Other observations

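The values of some further genes, several of them members of the lists above, are given here. The thiamine synthesis gene thiG rose with the curdlan phase in the mutant from 12.7 ± 0.106 to 475 ± 19.2 FPKM (5.12 ± 0.06 on the log2 scale), and ar14#2, a small RNA row, went from 14760 ± 2410 to 967900 ± 10700 (6.05 ± 0.21). With micro-oxygen in the wild type the phosphonate row phnG,phnH,phnI rose from 149.8 ± 5.15 to 563 ± 0.744 (1.90 ± 0.13) while phnD fell from 236 ± 7.38 to 71.8 (-1.70 ± 0.07). The thioredoxin gene trxA rose from 4622 ± 244 to 15220 ± 470 (1.72 ± 0.12).

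The bd oxidase genes cydA and cydB stood at 130 ± 2.02 and 129 ± 11.1 FPKM in the mutant at 24 h under normoxia, against 275 and 251 ± 9.73 in the wild type (-1.08, adjusted p = 3.99e-04 in limma, and -0.95). The row cydC,cydD had 247 ± 0.49 FPKM in the wild type and 166 ± 2.48 in the mutant at 24 h under normoxia, and 194 ± 3.03 and 311 ± 6.61 with micro-oxygen. The tricarboxylic acid cycle gene acnA was lower in the mutant with micro-oxygen (697 ± 45.1 against 1535 ± 26.1, -1.14 ± 0.11). In the growth phase the beta-glucan export gene chvA (186 ± 9.59 against 448 ± 38.2, -1.26 ± 0.07) and the succinoglycan row exoP#1 (179 ± 12.1 against 427 ± 37.9, -1.25) were lower in the mutant.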
